A study of Drosophila melanogaster with 6 samples.

How the data were processed

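Total RNA of 6 collections of Drosophila melanogaster embryos, 3 wild type (Oregon R, per the labels) and 3 rib1/ribP7, was measured on Affymetrix Drosophila Genome 2.0 arrays. Per the labels, embryos were collected for 8 h, aged for 11 h and sorted with an embryo sorter, RNA was extracted with Trizol, and 100 ng was amplified and labelled with biotin. The design text calls the collections independent, so each array is a separate biological sample. Scan dates and hybridization batches are not given in the sources used here and were not tested.

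The deposited values are log2 expression per probe set, normalized with RMA in Partek per the submitters' processing notes, with no version given. RMA makes the distribution of values alike between arrays, so a shift of most transcripts in 1 direction would be removed. It also compresses fold changes near background. No detection calls were used, and probe sets near the array median of about 5.5 may hold mostly background. Groups and replicate numbers were taken from the sample titles, and the design text gives the submitters' rule of at least 1.5-fold at p under 0.05.

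The table held 18952 probe sets. The 183 control probe sets were left out of the tests and used only for scaling and quality checks, which left 18769. Over all arrays the 3' minus 5' control signal was 3.60 to 4.06 log2 units for GAPDH and 1.49 to 1.93 for actin. The highest values were in wild-type replicate 3 for GAPDH and wild-type replicate 1 for actin. Signal was thus stronger at the 3' end on every array, and whether this makes probe sets of a gene disagree was not tested. Hybridization controls averaged 10.38, 10.55 and 10.78 log2 units in the wild-type arrays and 10.13, 10.16 and 10.28 in the mutant arrays. These averages did not overlap between the groups, and the cause was not tested. Gene names came from the platform annotation and were checked by gene identifier against a RefSeq gene table of assembly Release 6 plus ISO1 MT, in which 103 probe sets with an identifier had no match and no name changed. Of the tested probe sets 13647 had 1 gene symbol (11983 genes), 402 had several and 4720 are unnamed here. Genes were named only from probe sets with 1 symbol, and where a gene had several probe sets the brightest by mean over all arrays was used.

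Mutant and wild-type arrays were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, Benjamini-Hochberg over all tested probe sets, threshold 0.05). SEs are limma's moderated SEs. Exact permutation of 3 against 3 arrays cannot give a two-sided p under 0.1 and was not used. Named genes followed a rule set before the data were examined: rib, the 12 largest rises and 12 largest falls among called genes whose groups do not overlap, and for each gene list up to 2 called members each way, or the 2 with the smallest p where none passed. Other list members that passed are named from short counts and were chosen after their values were seen. All 1664 called probe sets had groups that do not overlap, as did 35.3% of all probe sets against 10% by chance.

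The 29 gene lists, also fixed before the data were examined, covered tissues (salivary gland, trachea, muscle, neurons, glia, fat body, haemocytes, midgut, hindgut and Malpighian tubules), cuticle, chitin, Osiris genes, junctions, secretion, dorsal closure, ecdysone, growth, metabolism, stress, immunity, early and maternal genes, and sex composition. They held 609 measured genes. The 28 lists with at least 3 measured genes were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the lists, with an estimated correlation and fry as alternatives. Many list members are unnamed here, so a list is a sample of its pathway.

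Replicate numbers were checked for pairing before any calls were compared. Deviations from the group means correlated at r = 0.37, 0.57 and 0.39 across probe sets for arrays with the same number, and between −0.33 and −0.14 for all other pairs across groups. The numbers may thus pair the samples, although the labels do not say what a number shares. Deviations within a group cancel out, so the negative values largely follow from the positive ones. With few arrays in each group few other matchings exist, so the pairing is not established. The fit without the block was set as the main one beforehand, and the blocked value is given where it changes a call or moves a count by over 1.5 times. Probe sets are not independent, so these correlations carry no p-value.

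Alternatives were the replicate block, a trended and robust prior, array weights (gene-by-gene method, taken up after the REML method did not converge on these data), median centring, cyclic loess, scaling on hybridization controls, a filter on the dimmest 40%, other probe set choices, a plain test without moderated variance, and each array left out. The pipeline was tested on simulated data for this comparison over 18769 probe sets with 200 changed. All of those changed were drawn from outside the dimmest 40%, so recovery among dim probe sets was not measured. It recovered 34% of those changed 1.5-fold, 54% at 2-fold, 84% at 4-fold and 98% at 8-fold, with 18 false calls among 153. That share of false calls was above the adjusted p threshold of 0.05. The probe sets called on the real arrays may therefore hold more false calls than the threshold nominally allows. The simulation took the SDs of 3 arrays per group as true and changed fewer probe sets than were called on the real arrays. Its recovery and its share of false calls thus need not carry over. With no effect simulated, 0 of 28 lists were called by camera, and a raised muscle list was called together with 1 other list. Noise was drawn independently for each gene, so this check cannot show how often camera calls lists whose genes are correlated. Estimated correlations within the real lists reached 0.89. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.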

Results

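Whole embryos mutant for ribbon (rib), a gene for a nuclear BTB-domain protein needed to shape the salivary glands and the trachea, were compared with wild-type embryos on Affymetrix arrays. Each group had 3 arrays, from independent collections of embryos at stages 11 to 16, so every value averages many tissues and a range of ages. Array medians lay between 5.51 and 5.56 log2 units, and the number of arrays limits the precision. The comparison asks which transcripts differ in level in embryos that carry the rib1 and ribP7 alleles.

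The rib transcript itself was higher in the mutants. Its only probe set measured 13.06 ± 0.32 log2 units in wild type (SD, n = 3) and 13.86 ± 0.08 in the mutants (SD, n = 3), a difference of 0.80 (SE 0.17), or 1.75-fold, with limma adjusted p = 0.0390. All 3 mutant arrays lay above all 3 wild-type arrays. The wild-type level was at percentile 99.3 of all probe sets, near the array maximum of 14.72, where signal can saturate. The labels do not say what either allele does to the transcript or where the probes lie relative to the lesions, so this level does not check the genotypes. The difference stayed between 0.62 and 0.91 when any array was left out, but the limma adjusted p rose to 0.0588 without wild-type replicate 2 and to 0.139, 0.155 and 0.117 without mutant replicates 1, 2 and 3.

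The largest rises among named genes were in NLaz, a secreted lipocalin, and eEF1alpha2, a form of translation elongation factor 1 alpha. NLaz went from 6.45 ± 0.70 to 11.80 ± 0.02 log2 units (SD, n = 3 each), a 41.0-fold rise with limma adjusted p = 0.000623. eEF1alpha2 rose by 4.64 (SE 0.14) from a wild-type level of 7.37 ± 0.27 (SD, n = 3), a 24.9-fold rise with limma adjusted p = 6.79e-05. The RNA-binding protein gene Syp rose by 4.15 on the log2 scale (SE 0.24), the POU-domain factor gene pdm3 by 3.88 (SE 0.49) and the ecdysone-induced transcription factor gene Eip93F by 3.64 (SE 0.31). Second probe sets of these genes moved less, by 0.94 for Syp, 1.06 for pdm3 and 0.20 for Eip93F. The serine protease gene Jon65Aiv rose by 3.77 (SE 0.08). The other 6 of the 12 largest rises were CG13748 (4.45), CG31198 (4.36), CG14421 (4.29), CG42807 (4.13), CG11370 (3.96) and CG13983 (3.94). In wild type most of these sat close to the array median of about 5.5, where background makes up much of the signal, so their fold changes may be understated.

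The largest falls among named genes were in CG31300, which went from 9.85 ± 0.86 to 4.63 ± 0.11 log2 units (SD, n = 3 each), 37.3-fold, and in Jon44E, another gene of the Jonah serine protease family, which went from 10.09 ± 0.22 to 5.05 ± 0.15 (SD, n = 3 each), 32.8-fold. The limma adjusted p-values were 0.00135 for CG31300 and 6.35e-05 for Jon44E. The eggshell gene clos fell by 4.57 on the log2 scale (SE 0.13) at 1 probe set, while its other probe sets gave −1.85 and −0.29. The chaperone gene Hsp68 fell by 3.75 (SE 0.35), the vitamin transporter gene Smvt by 3.69 (SE 0.42) and halo, a regulator of lipid droplet transport in the early embryo, fell by 3.31 (SE 0.35). The remaining falls were in CG10591 (−3.81), nur (−3.71), CG34025 (−3.58), SNCF (−3.50), Mabi (−3.40) and CG5568 (−3.31). In the mutants CG31300, Jon44E, clos, Smvt and CG34025 lay below the array median of about 5.5, in the range of background, so the sizes of these falls may be understated and their order is uncertain. Of the 24 genes named for their size of change, 21 passed limma's test in every fit that left out 1 array. CG34025, Mabi and CG5568 did not, with limma adjusted p-values of up to 0.118, 0.0645 and 0.0816.

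**Figure D1:**
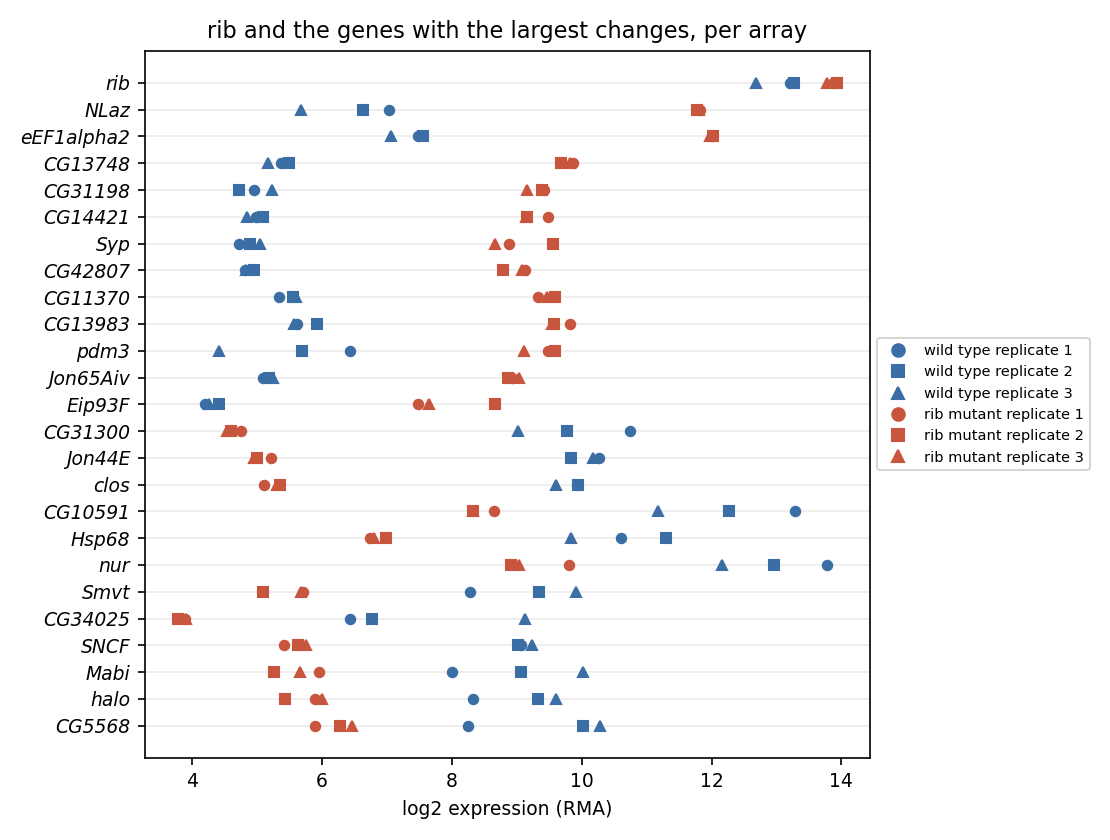
Log2 expression (RMA) of rib and of the 12 named genes with the largest rise and the 12 with the largest fall, where each point is 1 array, wild type in blue and rib mutant in red. For every gene shown the 3 mutant arrays lie on 1 side of the 3 wild-type arrays. The naming rule required this separation of all of them but rib.

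Across all 18769 probe sets, 1664 (8.87%) differed at a limma adjusted p under 0.05, with 1040 higher and 624 lower in the mutants. These stand for 902 named genes that were higher and 524 that were lower, with 3 genes counted both ways through different probe sets. The submitters' rule of at least 1.5-fold at an unadjusted p under 0.05 took in 2436 probe sets by limma, 1503 higher and 933 lower; the labels do not name the test behind their p. With the replicate number as a block, 2745 probe sets differed under limma, and with arrays scaled on their hybridization controls the calls were 2917 higher and 285 lower, as the median difference of all probe sets moved from −0.07 to 0.31. The limma count was 3674 without wild-type replicate 1, 891 without wild-type replicate 2, and 621, 603 and 607 without mutant replicates 1, 2 and 3.

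The wild-type arrays were less alike than the mutant arrays. The SD of the difference between any pair of arrays was 0.402 to 0.629 log2 units within wild type and 0.209 to 0.222 within the mutants. Of all probe sets, 80.8% had the larger SD in wild type. Mutant and wild-type arrays parted on the first principal component, which held 65.5% of the variance. Along it wild-type replicates 1, 2 and 3 also spread, at −0.17, −0.35 and −0.64, against 0.32 to 0.42 in the mutants. The 65.5% is thus not the group difference alone. The second component held 22.4% and set wild-type replicates 1 and 3 apart. Wild-type replicate 1 exceeded wild-type replicate 3 by a median of 2.30 log2 units over muscle genes, 1.72 over tracheal genes and 1.09 over Osiris genes.

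**Figure D2:**
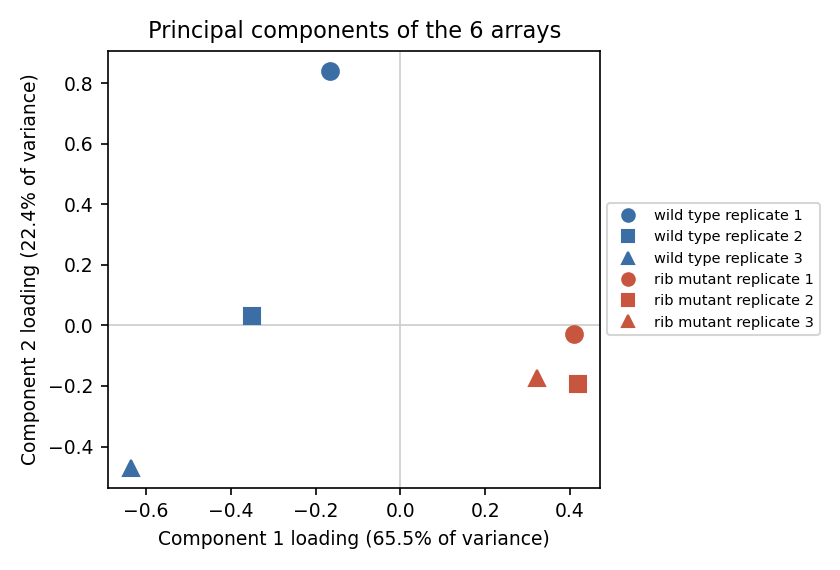
Loadings of the 6 arrays on the first (65.5% of variance) and second (22.4%) principal components, with 1 point per array. The 3 mutant arrays sit together at 0.32 to 0.42 on the first component. The wild-type arrays spread from −0.64 to −0.17 on the first and from −0.47 to 0.84 on the second.

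Most of the measured neuronal genes were higher in the mutants. Of 19 measured members of the neuron list 14 lay above 0, with a median of 1.29 log2 units, 2.45-fold. By limma's adjusted test 6 rose and none fell (12 and 0 when adjusted over the list alone). Rab3, a synaptic vesicle GTPase, rose 10.5-fold (log2 SE 0.62), ChAT, which makes acetylcholine, rose by 2.09 (SE 0.29), and Gad1, VAChT, nSyb and cac also passed. The list moved as a set in limma's camera test (adjusted p = 0.000132), although the adjusted p was 0.974 with an estimated correlation. List medians, relative to the mean over all arrays, were −0.17, −0.40 and −1.03 in the wild-type arrays and 0.64, 0.99 and 0.43 in the mutant arrays. Rab3 lost its call in 4 of the fits that left out 1 array (limma adjusted p up to 0.111) and ChAT in 2 (up to 0.0580).

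Muscle genes were also higher, with all 15 measured members above 0 and a median of 1.02 log2 units, 2.03-fold. Of these, 3 rose and none fell (4 and 0 when adjusted over the list alone), namely the Z-disc gene Zasp66 by 3.62 (SE 0.38), the actin gene Act87E by 1.92 (SE 0.16) and Obsc. Other probe sets of Zasp66 gave 2.08 and 0.25. The muscle list passed limma's camera test at adjusted p = 0.000401, with adjusted p = 0.974 with an estimated correlation, 0.110 by fry and 0.331 when arrays were scaled on hybridization controls. Its medians of 0.56, −0.79 and −1.60 in the wild-type arrays spanned a wider range than those of 0.60, 0.82 and 0.33 in the mutant arrays. None of 9 glial genes passed limma's adjusted test, and 3 were under an unadjusted p of 0.05. Among them gcm2 differed by 0.67 (limma adjusted p = 0.0596, 0.0297 with the replicate block) and Gli by −0.81 (limma adjusted p = 0.104, 0.0416 with the replicate block).

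The few heat shock genes measured on the list were lower, while Hsp83 and the Hsp70 genes are among its members unnamed here. Of 5 measured members, 3 fell and none rose (4 and 0 when adjusted over the list alone), with a median of −1.54 log2 units. Hsp68 and Hsp26 fell by 3.75 (SE 0.35) and 2.57 (SE 0.25), and DnaJ-1 was the third. The heat shock list passed limma's camera test at adjusted p = 0.00258, with adjusted p = 0.974 with an estimated correlation. Its medians were 1.34, 1.09 and 0.34 in the wild-type arrays and between −0.86 and −0.63 in the mutant arrays. Among 8 genes with the Hsp stem, a grouping made after results had been seen, 2 fell and none rose. Their median was −0.24 (limma camera adjusted p = 0.312). Osiris genes, a clustered family of membrane proteins, had 23 of 24 measured members below 0 and a median of −0.32, but no member passed limma's adjusted test on its own and 2 were under an unadjusted p of 0.05. Osi15 differed by −3.87 (SE 1.43, limma adjusted p = 0.160) and Osi3 by −0.29 (SE 0.09, limma adjusted p = 0.105). As a set the Osiris list passed limma's camera test at adjusted p = 0.0323, with adjusted p = 0.974 with an estimated correlation, 0.193 by fry, 0.0891 with array weights, 0.0604 with cyclic loess and 0.142 without wild-type replicate 1, whose median of 0.89 stood above the other arrays.

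Dorsal closure and JNK pathway genes had a median of 0.44 log2 units over 10 members, of which Jra, the fly Jun gene, rose by 0.68 (SE 0.10) and none fell (2 and 0 when adjusted over the list alone). The list passed limma's camera test at adjusted p = 0.0323, with adjusted p = 0.974 with an estimated correlation, 0.242 by fry, 0.0973 without wild-type replicate 3 and 0.108 without mutant replicate 2. It also missed the threshold with arrays scaled on hybridization controls (limma adjusted p = 0.437), array weights (0.127), cyclic loess (0.0749), the mean probe set of each gene (0.0528), and both without the dimmest 40% of probe sets and with bright genes as background (0.102 each). In all, 5 of 28 lists passed camera, the others lying between limma adjusted p-values of 0.0936 and 0.938, and none did with an estimated correlation, where the lowest unadjusted p was 0.0659 for neurons. Some lists passed limma's camera test only in another setting. Without wild-type replicate 1 these included the secretory pathway and glycolysis (both adjusted p = 0.0233, medians 0.21 and 0.63) and glia and haemocytes (both 0.0375, medians 0.82 and 0.39), and without wild-type replicate 2 polarity and adherens junctions (0.0225, median 0.24). With arrays scaled on hybridization controls, salivary gland (0.00468), cell cycle (0.00940) and early and maternal genes (0.0118) were lower relative to other genes by limma's camera test, although their medians were 0.32, 0.10 and 0.25, as that scaling raised the mutants against wild type over all probe sets. Each of the 10 ways to split the 6 arrays into equal groups moved at least 5 lists. By fry, which asks whether a list moves one way without comparing it with other genes, neurons and heat shock (both limma adjusted p = 0.0360), ribosome biogenesis and apoptosis and stress (both 0.0304) passed, and none passed when the replicate block was added.

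**Figure D3:**
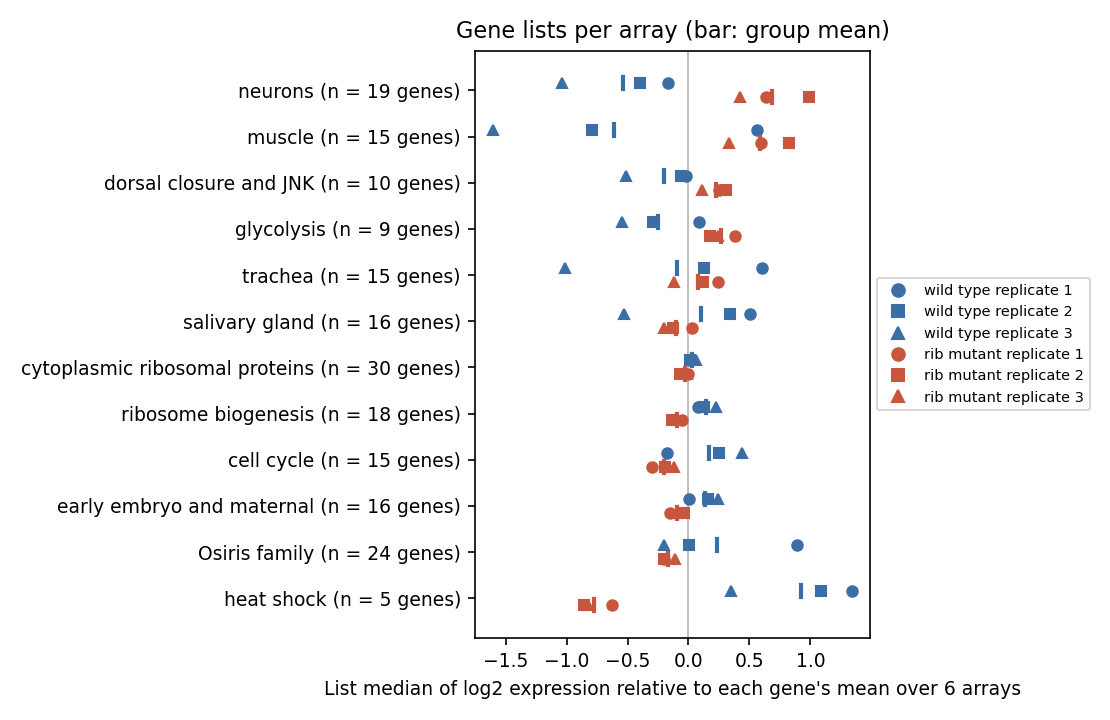
Median over the genes of a list of log2 expression relative to each gene's mean over all 6 arrays, for 12 of the lists, with 1 point per array and a bar at each group's mean. Neuron and heat shock medians do not overlap between the groups, while wild-type replicate 1 reaches the mutants for muscle. Medians also do not overlap for dorsal closure and JNK, glycolysis, cytoplasmic ribosomal proteins, ribosome biogenesis, and early and maternal genes. Of these further lists only dorsal closure and JNK passed limma's camera test in the main fit.

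Among tissues that rib shapes, the salivary gland list held 16 measured genes, of which nur fell by 3.71 (SE 0.44), CG14756 fell by 2.64 (SE 0.56) and none rose (2 lower and 0 higher when adjusted over the list alone). The list median was −0.06 (limma camera adjusted p = 0.413). Without wild-type replicate 3, the limma camera adjusted p was 0.00567 with a median of −0.46. Of 15 tracheal genes only pio, which encodes a luminal matrix protein, passed, with a rise of 1.81 (SE 0.34). Other probe sets of pio gave 0.04 and 0.16. Its list median was 0.17 (limma camera adjusted p = 0.559). In the secretory pathway list Surf4 fell by 1.04 (SE 0.15), the only call among 33 members. Mer fell by 0.71 (SE 0.15), the only call among 17 polarity and adherens junction genes, and no septate junction gene of 14 passed limma's adjusted test, with 1, Gli, under an unadjusted p of 0.05 (limma adjusted p = 0.104, 0.0416 with the replicate block).

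Cuticle genes showed rises without a shift of the whole list. Of 103 members 9 rose and none fell (9 and 1 when adjusted over the list alone), among them Cpr49Ag by 2.81 (SE 0.13) and Lcp9 by 2.45 (SE 0.14), while the median was −0.08 and the mean 0.01 (limma camera adjusted p = 0.938). In chitin metabolism Idgf3 rose by 1.59 (SE 0.19), the only call among 21. Another probe set of Idgf3 gave 0.65. Ecdysone genes went both ways, with 3 rises and 3 falls among 17. The steroid synthesis genes spo and dib fell by 2.85 (SE 0.13) and 2.38 (SE 0.11), as did sad, while the response genes br and Eip78C rose by 2.76 (SE 0.63) and 2.09 (SE 0.34), as did ImpE3. The br call had limma adjusted p = 0.0492, and its other probe sets ranged from −0.05 to 1.55. In the midgut list of 23, Jon65Aiv and Jon65Aiii rose and Jon44E fell. The median and mean of the cuticle, chitin, midgut and translation factor lists differed in sign, and fry gave the ecdysone list a lower direction against a positive median of 0.39.

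Metabolic and defence lists held a few calls each. Gapdh1 and Eno, enzymes of glycolysis, rose by 1.79 (SE 0.19) and 1.01 (SE 0.14), 2 of 9 members. In the fat body list FASN1 and Desat1, enzymes of fatty acid synthesis and desaturation, rose by 2.28 (SE 0.29) and 0.95 (SE 0.11), 2 of 7 members. GstD1 and the cell death gene skl rose by 1.58 (SE 0.22) and 0.93 (SE 0.16), 2 of 8 apoptosis and stress genes. The phagocytic receptor gene eater rose by 1.10 (SE 0.08), 1 of 20 haemocyte genes. PGRP-LB rose by 1.02 (SE 0.10) and Mtk, an antimicrobial peptide gene, fell by 0.78 (SE 0.13) among 7 immunity genes. The wild-type level of PGRP-LB, 4.93, also lay below the array median. None of 11 hindgut and Malpighian tubule genes passed limma's adjusted test, with 3 under an unadjusted p of 0.05, drm and lin among them at −0.72 and −0.32.

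Of 18 ribosome biogenesis genes 3 fell and none rose (8 and 1 when adjusted over the list alone), including Nop60B by 0.92 (SE 0.09) and Fib, which encodes fibrillarin, by 0.69 (SE 0.14). With a median of −0.32, that list missed the threshold in limma's camera test (adjusted p = 0.0936), but passed with cyclic loess (0.0214) and without mutant replicate 1 (0.0476). RpL27 fell by 1.34 (SE 0.10), the only call among 30 cytoplasmic ribosomal protein genes. Of 69 mitochondrial ribosomal protein genes, mRpS28 and mRpL35 rose and mRpS6 and mRpL4 fell, and the list passed limma's camera test only without wild-type replicate 2 (adjusted p = 0.0225, median −0.20). Among 40 proteasome genes Rpn2 and Rpn5 rose and Prosbeta4 fell, by 1.17 (SE 0.23). No translation factor gene of 24 passed limma's adjusted test, with 5 under an unadjusted p of 0.05. PCNA fell by 0.94 (SE 0.21), the only call among 15 cell cycle genes (limma adjusted p = 0.0486). The cell cycle list passed limma's camera test without wild-type replicate 1 (adjusted p = 0.0221, median −0.46). Of 16 early and maternal genes 4 fell and 1 rose, among them halo at −3.31 (SE 0.35) and osk at −2.50 (SE 0.56), while the yolk protein gene Yp3 rose by 2.07 (SE 0.13). The 1 measured gene of the sex composition list, msl-2, differed by −0.05 (limma adjusted p = 0.807). When adjusted over the list alone, calls were 0 higher and 1 lower for mitochondrial ribosomal proteins, 1 and 1 for haemocytes, 0 and 0 for the cell cycle, 3 and 1 for glycolysis and for apoptosis and stress, 1 and 2 for immunity and 1 and 5 for early and maternal genes, and the counts of every list not given such a count were as over all probe sets.

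Of 64 genes besides rib that the naming rule chose and that passed limma's test, 39 passed in every fit that left out 1 array. Besides CG34025, Mabi, CG5568, Rab3 and ChAT, those that missed it in at least 1 such fit were mRpS28, mRpL35, mRpL4, Fib, Rpn5, Rpn2, Prosbeta4, CG14756, Surf4, pio, Mer, Jra, PCNA, br, Eip78C, Eno, GstD1, skl, Mtk and osk, with limma adjusted p-values of up to 0.180 for PCNA. All 64 passed with the replicate block. Of 15 other genes that passed and are named from short counts or families, all passed with the replicate block and 7 in every fit that left out 1 array, while VAChT, nSyb, cac, sad, ImpE3, Rrp1, Rrp4 and Rrp40 missed it in at least 1, with limma adjusted p-values of up to 0.161 for cac.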

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

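The splits of the arrays were planned, while the search of the control probe sets and the tests of array position, of chromosome 2 and of the genes beside rib were chosen only after results had been seen, and those of chromosome 2 and of the genes beside rib were then replaced by other forms with the first results known. A signal stood out among probe sets outside the comparison. The control probe set AFFX-Dm-U43284-1_s_at measured 8.68 log2 units in mutant replicate 1, against 5.23 to 5.45 in the wild-type arrays and 5.66 and 5.90 in the other mutants, the only 1 of 144 such control probe sets that stood more than 2-fold above every wild-type array.

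With 3 arrays against 3 there are 10 splits, too few for a share under 0.05. The real split gave 1664 differing probe sets against at most 0 in the others by limma, so 1 of 10 splits reached it, and 2436 past the submitters' rule against at most 432, or 37 among the others that part all 3 pairs, again 1 of 10. For gene lists the real split moved 5 by camera, all 10 splits moved as many, and the highest other moved 14. Calls in every split may reflect correlation between the genes of a list beyond the preset 0.01 (estimates ran from −0.13 to 0.89, and with them 0 lists moved) or a structure of the samples, which cannot be told apart here. Without single arrays 4 to 9 lists moved.

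By limma's camera test at the preset correlation muscle and neuron genes were higher and Osiris genes lower in the mutants, but all 3 calls were lost with an estimated correlation (adjusted p = 0.974 each), the muscle call also by fry (0.110) and with arrays scaled on hybridization controls (0.331), and the Osiris call, with 0 of 24 members passing alone (2 at an unadjusted p under 0.05), also by fry (0.193), with array weights (0.0891) or cyclic loess (0.0604) and without wild-type replicate 1 (0.142). The wild-type arrays differ in these lists too, replicate 1 minus replicate 3 being 2.30 for muscle, 0.76 for neurons (bootstrap 95% interval over genes −0.02 to 1.37) and 1.09 for Osiris genes (−0.04 to 2.88), and mutants at 1 position on that gradient should have both muscle and Osiris genes on the same side of wild-type replicate 2, but the mutant mean minus that array was 1.30 (0.78 to 1.55) and −0.17 (−0.43 to −0.10). Other values went both ways, since cell cycle genes (−0.35, against −0.81 along the gradient) and a correlation over 11983 genes, which are not independent replicates (Pearson's r = 0.350, Spearman's rho = 0.443), go with the gradient, while tracheal genes (−0.06, −0.28 to 0.16, against 1.72), chitin genes (−0.10, −0.28 to 0.00, against 1.53) and heat shock genes (−1.72, −4.46 to −0.65, against 0.76) do not follow muscle along it. Mutant collections older than every wild-type array, past a peak of Osiris expression, may also account for the pattern. The lowest mutant array exceeded the highest wild-type array by 0.60 log2 units in the neuron median. That gap is part of the pattern to be explained and decides nothing without a time course. In the muscle median mutant replicate 3 (0.33) lay below wild-type replicate 1 (0.56), as did all mutants (at most 0.24, against 0.60) in the tracheal median. The Osiris interval along the gradient includes 0, so the Osiris values cannot decide the first explanation. The intervals resample genes and do not measure the spread between arrays. The trachea is shaped by rib itself, so its median need not follow age. Some of the other values argue against each explanation without excluding it. The comparison for the first rests on 1 wild-type array, and the course of these lists with age was not measured. Age and genotype thus cannot be told apart, and an effect of rib stays open and untested.

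Calls were spread over the genome, at 9.74% to 12.5% of the genes on each large chromosome arm and 14 of 65 genes (21.5%) on chromosome 4. Of 1343 called genes with a known arm, 788 or 58.7% lay off chromosome 2, which carries rib (exact binomial 95% interval 56.0% to 61.3%). That is far above the 5% of false calls that the threshold nominally allows, and above the 18 of 153 in the simulated data. Differences acting in cis on the mutant second chromosome cannot account for the calls off it, so they are not the whole cause. This form was chosen with the odds ratio below known, so its outcome was foreseeable and it serves only as a description. Calls spread evenly over the arms would give a like share whatever their source, so it does not tell other causes apart. The first form of this test, an odds ratio of 1.12 for being called on chromosome 2 (0.993 to 1.26, Fisher's exact test, two-sided p = 0.0613), bears on such cis effects alone. Among the 50 measured genes on each side of rib 15 of 100 were called against 11.2% of all genes, an odds ratio of 1.40 (0.747 to 2.44, Fisher's exact test, two-sided p = 0.263), so a raised share near rib stays open, and the first form, the share of all calls found there, was dropped because 100 genes could never hold most of them. Effects in trans of variants on chromosome 2, background differences elsewhere between Oregon R and the mutant stock, and an effect of rib itself stay open, since the labels give no matched control stock.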

How the results depend on the processing

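All settings here were set beforehand except the replicate block combined with an estimated correlation or fry, and the gene-by-gene method for array weights, chosen after seeing the data. Of 1664 differing probe sets, 1601 were also called with the replicate block, in the same direction, when 2745 differed (1689 higher, 1056 lower), and the block changed no list call by camera. Array weights gave 4371 (2243 higher, 2128 lower), scaling on hybridization controls 3202 (2917 higher, 285 lower) and a plain test without moderated variance 594 (388 higher, 206 lower). Leaving out single arrays gave 603 to 3674 (422 to 2011 higher, 166 to 1663 lower). Fewer arrays lower the power, and the cause of the other changes was not tested. By the submitters' rule only scaling on hybridization controls moved a count by over 1.5 times (3270 higher, 351 lower). rib stayed higher in every setting run for it, which left out the filter on the dimmest 40%, but missed the limma threshold with cyclic loess (0.81, adjusted p = 0.0559), in the plain test (0.80, 0.133) and in 4 of the fits without 1 array (differences of 0.62 to 0.91 over all 6 such fits); its adjusted p ranged from 0.00784 to 0.155 over these settings. Gene lists that moved numbered 3 with array weights (1 lower), and with hybridization controls 1 was higher and 5 lower. With an estimated correlation 0 moved (0 higher, 0 lower), with the replicate block and an estimated correlation 0 (0 and 0) and with the replicate block and fry 0 (0 and 0), beside 4 by fry alone. Without single arrays 4 to 9 moved (2 to 7 higher). Of 64 other genes that the naming rule chose and that passed, 33 passed in every such setting and 39 in every fit without 1 array, and none of these changed sign in any of them. Signal near background limits the dim probe sets, where a rise from 5 log2 units has an uncertain fold.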

Other observations

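The tests here were chosen after results had been seen, and the genes named were chosen after their values were seen. Of 11 glutathione S-transferase genes of the GstD group, 5 rose and 1 fell by limma, GstD3 rising by 1.95 (SE 0.24) and GstD4 by 0.89 (SE 0.08) on the log2 scale. The wild-type level of GstD4, 4.72, was in the range of background. Of 13 GstE genes 3 fell and none rose, with GstE5 down by 2.09 (SE 0.08). Other detoxification families held calls both ways, with 6 rises and 7 falls among 83 Cyp genes and 6 rises and 1 fall among 35 Ugt genes (limma camera adjusted p = 0.628 and 0.889). Among 20 autophagy genes 3 rose and none fell, Atg101 by 1.16 (SE 0.13). Of 9 genes with the Rrp stem 3 fell and none rose: Rrp1, a DNA repair gene, fell by 0.63 (SE 0.12), and Rrp4 and Rrp40, subunits of the RNA exosome, fell by 0.93 (SE 0.16) and 0.74 (SE 0.14). The idea that families sharing a symbol stem moved as sets beyond the fixed lists was tested on 53 families of at least 8 genes, and 0 passed limma's camera test (7 at an unadjusted p under 0.05, and 1 with an estimated correlation). The lowest adjusted p, 0.111, was shared by GstD, GstE, Atg, Rrp and Usp (1 of 15 genes up and 1 down). The bound for this test was revised once these counts were known, since a missed threshold excludes nothing, and the idea stays open.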
